A study of Bos taurus with 6 samples.

How the data were processed

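Oocyte RNA of 3 cows was compared on 6 arrays with 2 channels, 1 of control oocytes and 1 of oocytes from the same cow under GnRH antagonist, each pair in both dye orientations. Per the labels' protocols, RNA was amplified to antisense RNA before it was labelled with Cy3 and Cy5. Group and cow of each channel were taken from the labels, which also state that each cow was its own control, so that replicates are separate animals and both values of a cow are paired by design. Slides were inferred from a number in the names of the scanner files, since no label states them. By that number the 6 arrays lay on 3 slides, 1 of which held 4 arrays from all 3 cows. These were all 3 arrays with antagonist in Cy5 and cow 2's array with control in Cy5. Dye orientation was thus in part confounded with slide.

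The scanner files hold raw spot intensity, per the file headers, as the mean and trimmed mean of the pixels at 635 nm (Cy5) and 532 nm (Cy3) with the local background of each spot, and no correction had been applied. Columns were picked by wavelength, since their order differed between files, and 14 rows of column statistics per file were left out. The scanner, its software and its settings are not given in the sources used here. A value table deposited by the authors holds log2 ratios, 1 per probe and array; set against the scanner values it was found already turned to antagonist over control on every array, with slopes of 0.99 to 1.00 on bright probes, and the medians of its columns were 0.0010 and 0.0015 for cow 1, -0.0027 and 0.00081 for cow 2, and 0.0018 and 0.00039 for cow 3 (control in Cy5 first). How those ratios were normalized is not known. The table served as an alternative.

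Of 45220 spots per array, 105 were left out because the image analysis had marked them as ignored on at least 1 array, 102 of them probes. Intensities were corrected with limma's normexp method (offset 50) and normalized by loess within each array, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. No normalization between arrays was applied. A probe was tested when its raw foreground exceeded the mean plus 2 SD of the 152 negative control spots of its channel in at least 3 of 6 readings of either condition, which kept 32527 probes; 20733 exceeded it in all 12 readings. By spot mean no probe was saturated, and the highest spot mean of each array lay between 38906 and 41132. Control spots and single pixels were not checked for saturation, and whether the brightest ratios were compressed was not tested. The median raw spot intensity lay between 191 and 272 in Cy5 and between 219 and 277 in Cy3, against means of the negative controls between 154 and 222 and between 170 and 214, so that the precision of dim probes is limited by signal over background.

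Log ratios were turned to antagonist over control, both arrays of a cow were averaged, and the 3 values were tested against 0 with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg over probes). A second count took unadjusted p-values under 0.05 with at least 1.5-fold change. Differences between cows and the dye term were tested in a fit of the 6 arrays with an effect for each cow and a dye term. Gene symbols came from the array's platform annotation, which can be old: 21790 probes carry 1 symbol, none carries several, and 92.2% of the 12314 symbols tested occur in RefSeq's ARS-UCD assembly table. Each gene was represented by its brightest probe, and 27 gene lists with at least 5 measured genes were tested by camera with a preset correlation of 0.01, and again with an estimated correlation and with fry, which tests whether a list's genes move one way on balance.

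The genes named were fixed by rule before the data were examined, as were the tests, lists and alternatives unless stated otherwise. The rule took the 12 largest rises and falls among single-symbol probes that passed correction with the same sign on all 6 arrays and, since fewer than 10 did, among those at unadjusted p under 0.05 and 1.5-fold; the 3 members of smallest p of each of the 6 lists with the smallest camera p; and a fixed set of oocyte, follicle and blood genes. Where the rule left open whether a list that passed replaces those 6, all 6 were named.

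The fits were tested on simulated data with the spread and dye effects of these arrays for 32527 probes but with independent probes. For antagonist against control, 86.0% of 50 probes simulated at 2-fold and 4.0% of 50 at 1.41-fold were recovered at an adjusted p under 0.05. The simulation gave changed probes the spread of all probes, whereas the 248 real probes at 2-fold or more had a median SD over cows of 0.59, against 0.11 for all probes tested, and none of them passed. Alternatives covered the background correction (none, plain subtraction, offset 16), normalization (median centring, Aquantile), the filter on dim probes, the treatment of a cow's 2 arrays, the pairing, the variance model, the authors' ratios, the slide, each dye orientation and each cow left out.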

Results

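The series measured messenger RNA levels in oocytes of 3 Holstein cows on 2-colour oligonucleotide arrays. Each cow received follicle-stimulating hormone (FSH) at 12 h intervals for 3 days and then no FSH for a coasting period of 68 h, the interval in which follicles continue to develop on the animal's own gonadotropins. Each cow went through this protocol once alone (control) and once with a gonadotropin-releasing hormone (GnRH) antagonist given throughout coasting, with at least a month between both. A GnRH antagonist blocks the pituitary receptor through which GnRH drives luteinizing hormone (LH) secretion, and the labels name the compound as cetrotide. Oocytes were aspirated and stripped of cumulus cells before RNA extraction and amplification. Both RNAs of a cow shared an array, and each pair was hybridised again with the dyes exchanged, so that 6 arrays gave 3 replicates, 1 per cow. Spots were above the negative controls for 55.8% to 77.5% of probes per channel, and 32527 of 43794 probes were tested. All ratios below are log2 antagonist over control, given as mean ± SD over the cows (n = 3), and the small number of cows limits their precision.

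The comparison of antagonist with control oocytes asks how withdrawing GnRH action during coasting altered the transcripts stored in the oocyte. The messenger RNAs of cytosolic ribosomal proteins rose as a group with the antagonist, by a median of 0.23 over 67 measured genes, and their median was above 0 in each cow, at 0.19, 0.47 and 0.18 in cows 1, 2 and 3; 17 of the 67 genes had negative ratios. This call by limma's camera, with a preset correlation between genes, was lost with an estimated correlation (adjusted p = 0.86) and with fry (adjusted p = 0.32). No single probe passed correction for multiple testing. Among probes that did not pass it, the transcripts of NLRP5, a maternal-effect gene needed for early cleavage, of ZP3, a zona pellucida glycoprotein, and of MOS, the kinase that activates the MAP kinase pathway in meiosis, had positive mean ratios in each cow. The transcripts of CDK1, the catalytic subunit of maturation-promoting factor, and of ZAR1, a maternal-effect RNA-binding protein, had negative ratios in each cow. Such agreement was common, since 36.0% of all probes tested had the same sign in 3 cows. In the same fixed gene set BMP15, CCNB1 and GPR3, among others, had mixed signs. The oocyte and maternal-effect list did not pass as a group (adjusted p = 0.21).

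The ribosomal protein genes formed the one list of 27 that passed limma's camera set test with a preset correlation between genes (adjusted p = 6.3e-06). With an estimated correlation the adjusted p was 0.86, and with fry it was 0.32. Of the 67 genes, 50 had a positive and 17 a negative mean ratio, and 35 had positive ratios in all 3 cows against 7 with negative ones. At an unadjusted p under 0.05, 26 genes were higher, 2 were lower and 39 did not pass. None passed over all probes tested, and adjusted over the list alone 6 passed, all higher. RPS12 had a ratio of 0.67 ± 0.036, RPS19 0.96 ± 0.20 and RPLP1 0.97 ± 0.23, each higher on all 6 arrays. RPL28, at 2.25 ± 0.59, had the largest ratio of these 6, and its 2 dimmer probes gave 0.65 and 0.81. The list's median was 0.36 on the 4 arrays whose scanner files share a slide number. These were both arrays of cow 2 and the antagonist-in-Cy5 arrays of cows 1 and 3. Their fit weighted cow 2 most, so slide was not separated from cow. The median was 0.12 when arrays were centred on the median without loess. Without cows 1, 2 and 3 in turn it was 0.33, 0.14 and 0.31.

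**Figure D1:**
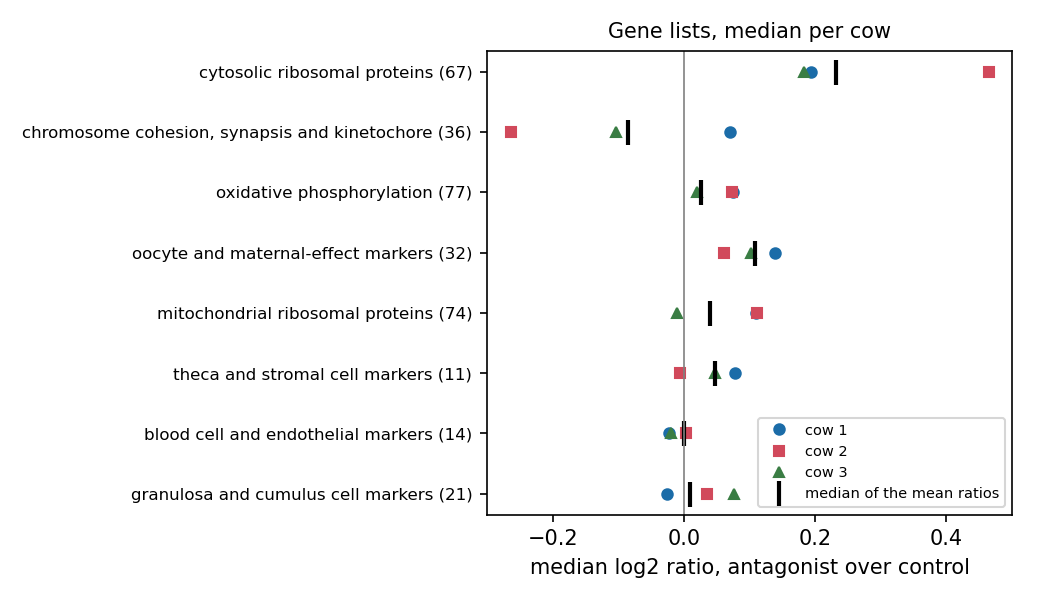
Median log2 ratio of antagonist over control (horizontal axis) of the genes of 8 lists, with the number of measured genes in brackets. Circles, squares and triangles are cows 1, 2 and 3, and the bar is the median of the genes' mean ratios. The cytosolic ribosomal protein genes lie above 0 in all 3 cows, and the granulosa and blood cell markers lie close to 0. The blood cell markers were dim, with a mean log2 intensity of 7.84.

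The other 26 lists did not pass camera, with adjusted p-values from 0.14 upward. Genes of chromosome cohesion, synapsis and the kinetochore had the next smallest p (adjusted p = 0.14), a median of -0.08 and 28 of 36 members below 0, but the medians were 0.07, -0.26 and -0.10 in cows 1, 2 and 3. Within it the cohesin subunit gene SMC1B had a ratio of -0.55 ± 0.14, while the kinetochore gene KNTC1 had 0.41 ± 0.14 and the synaptonemal complex gene SYCE2 0.50 ± 0.24; 2 other probes of SYCE2 gave -0.10 and -0.02. The list's result depended on the cows: without cow 1 it passed at an adjusted p of 0.0043, with a median of -0.18, and without cow 2 the median was -0.05 (adjusted p = 0.69). On the arrays with antagonist in Cy5 the adjusted p was 0.86. On the shared slide the list passed at 0.025 with a median of -0.20. That slide held both arrays of cow 2 but only the antagonist-in-Cy5 arrays of cows 1 and 3. The fit took these arrays as independent values and weighted cow 2 most.

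Genes of the mitochondrial respiratory chain and ATP synthase had a median of 0.03 over 77 genes (adjusted p = 0.17), and 47 lay above 0. None passed over all probes, and 5 passed when adjusted over the list alone. Of these NDUFA3, a subunit of complex I, had a ratio of 1.21 ± 0.20, NDUFA11 had 0.56 ± 0.10, and ATP5S had -0.48 ± 0.034. The other probe of NDUFA3 gave 0.38, those of NDUFA11 gave 0.21 and 0.41, and those of ATP5S gave -0.58 and -0.04. Mitochondrial ribosomal protein genes had a median of 0.04 over 74 genes (adjusted p = 0.26), with 41 above 0, and 12 passed adjusted over the list alone. MRPS11 had a ratio of 0.98 ± 0.23, MRPS24 0.51 ± 0.087 and MRPS25 0.48 ± 0.11; the 3 other probes of MRPS11 ranged from 0.57 to 1.38, and that of MRPS25 gave 0.20. Without cow 3 both lists passed camera, at adjusted p-values of 0.024 and 0.046, but without cow 1 the adjusted p was 0.60 for both. The respiratory chain median turned to -0.03 on the arrays with antagonist in Cy5, and the mitochondrial ribosomal median to -0.02 with median centring.

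Oocyte and maternal-effect markers had a median of 0.11 over 32 genes (adjusted p = 0.21), with 21 above 0 and none that passed adjusted over the list alone. NLRP5 had the largest ratio of the named members, 1.11 ± 0.35, followed by ZP3 at 0.60 ± 0.15, whose 2 other probes gave 0.63 and 0.67. TCL1A had 0.27 ± 0.048. Without cow 2 the list passed at an adjusted p of 0.012, and without cow 1 the adjusted p was 0.69. The list's median fell to 0.02 with median centring (adjusted p = 0.85) and to 0.0095 on the arrays with antagonist in Cy5 (adjusted p = 0.86). Of the secreted oocyte growth factors, GDF9 had a ratio of 0.28 ± 0.24 and BMP15 0.0037 ± 0.19, and neither had an unadjusted p under 0.05 by limma. ZAR1 had -0.34 ± 0.23, with a negative ratio on all 6 arrays and an unadjusted p of 0.040 by limma.

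Among regulators of meiotic arrest and resumption, MOS had a ratio of 0.90 ± 0.40, positive on 5 of 6 arrays, and its 3 other probes ranged from 0.23 to 0.81. CDK1 had -0.63 ± 0.28, negative on all 6 arrays. CCNB1, which encodes the cyclin partner of CDK1, had -0.11 ± 0.22. PDE3A, the oocyte phosphodiesterase, had -0.10 ± 0.068, and GPR3, the receptor that keeps cyclic AMP high in the oocyte, had 0.02 ± 0.28. None of these passed correction, and for CCNB1, PDE3A and GPR3 limma's unadjusted p was also above 0.05. PDE3A and GPR3 were dim, with mean log2 intensities of 7.87 and 7.80, which limits the precision of their ratios.

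Markers of the cells that surround the oocyte did not pass the test as groups. Granulosa and cumulus cell markers had a median of 0.01 over 21 genes (adjusted p = 0.78), and blood and endothelial markers -0.00014 over 14 genes (adjusted p = 0.78). The blood and endothelial list was the dimmest list tested, with a mean log2 intensity of 7.84, so its median near 0 says little. Theca and stromal markers had 0.05 over 11 genes (adjusted p = 0.37). All 11 had positive mean ratios, but only 1 was positive in all 3 cows and none had an unadjusted p under 0.05 by limma. The gap junction gene GJA1 had a ratio of 0.17 ± 0.15. CYP19A1, the aromatase of granulosa cells, had -0.04 ± 0.031, the FSH receptor gene FSHR -0.05 ± 0.22, and the haemoglobin genes HBA and HBB 0.03 ± 0.081 and 0.01 ± 0.055. These 4 were dim: of 6 readings per condition, CYP19A1 was above background in 5 and 5 with antagonist and control, FSHR in 3 and 3, HBA in 5 and 4 and HBB in 3 and 2. No tested probe carried the symbol of the LH receptor gene LHCGR. Whether its signal was too low or the annotation has no probe for it was not checked. Among theca and stromal markers FN1 had 0.14 ± 0.16, PDGFRA 0.08 ± 0.082 and VIM 0.60 ± 0.82, the last with ratios of 0.33, -0.04 and 1.52 in cows 1, 2 and 3. PDGFRA was dim too, above background in 4 of 6 readings with antagonist and 3 with control.

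Across all probes, limma called 0 of 32527 at an adjusted p under 0.05, and the lowest adjusted p was 0.28. At an unadjusted p under 0.05 there were 4143 probes (12.7%), of which 2185 were higher and 1958 lower; flipping the sign of whole cows gave 331, 585 and 2930. With a change of at least 1.5-fold in addition, uncorrected, 793 probes remained, 630 higher and 163 lower with the antagonist. Of these, 498 had a gene symbol. Centring arrays on the median without loess gave 566 higher and 338 lower. The 3 arrays with antagonist in Cy5, taken alone, gave 744 higher and 905 lower, and the 3 with control in Cy5 gave 1701 and 569. In both of these the dye effect is not cancelled. With loess, the 1.5-fold count was 2418 without cow 1, 434 without cow 2 and 451 without cow 3. When the 6 arrays entered singly with the cow as a random replicate block and a dye term, 848 probes passed at an adjusted p under 0.05, 614 of them higher; this fit assumes 1 correlation for all probes.

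The genes named next were picked from this uncorrected set by the size of the ratio, among the 721 probes with the same sign on all 6 arrays and only where a probe was the brightest of a gene with a symbol; none passed correction. LIG1, the DNA ligase that joins Okazaki fragments, had the largest, 3.09 ± 0.75, or 8.53-fold. It was followed by MED29, a Mediator subunit, at 2.33 ± 0.96, C10H14orf179 at 2.25 ± 0.36, RPL28 as above, WRAP53, which guides telomerase to Cajal bodies, at 2.14 ± 0.91, and SPIRE2, an actin nucleator that acts in oocyte division, at 2.10 ± 0.59. KRT19, an epithelial keratin, had 2.09 ± 1.12, and THAP4, IP6K3, PPIE, RNF31 and VPS8 had ratios between 1.87 and 1.96. The negative ratios were smaller. IFT52, a component of intraflagellar transport, had -1.08 ± 0.50, ELP4, an Elongator subunit, -1.04 ± 0.75, DNAJC21 -0.97 ± 0.69, TXNIP, an inhibitor of thioredoxin, -0.92 ± 0.38, and MAGOH, a core protein of the exon junction complex, -0.92 ± 0.63. SFT2D1, STXBP3, UBL3, FCHSD2, JMJD1C, ATF1 and CAMTA1 had ratios between -0.90 and -0.83. Other probes of the same gene differed from several of these values: those of MED29 gave 0.30 and 0.48, those of PPIE -0.09 and 0.28, those of RNF31 0.27 and 0.28, that of ELP4 -0.00088, that of TXNIP -0.24, that of UBL3 -0.46, those of FCHSD2 -0.0086 and 0.05, and those of ATF1 -0.26 and 0.03. That of IFT52 gave -0.85.

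**Figure D2:**
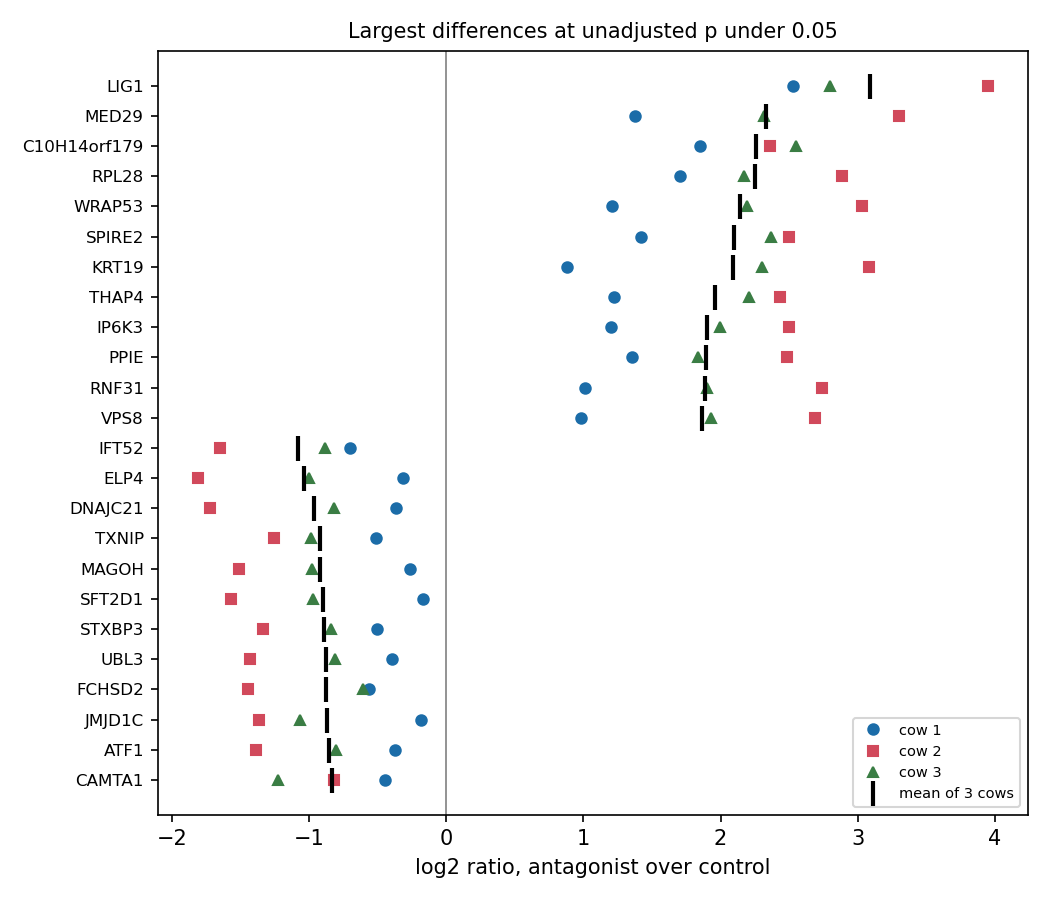
Log2 ratio of antagonist over control (horizontal axis) of the 12 genes with the largest positive and the 12 with the largest negative mean ratios among those at unadjusted p under 0.05, at least 1.5-fold and of the same sign on all 6 arrays. Circles, squares and triangles are cows 1, 2 and 3, and the bar is their mean. No gene passed correction, and the ratios run from 3.09 for LIG1 to -1.08 for IFT52.

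The size of the ratios varied from cow to cow. The SD of the ratios over probes was 0.20 in cow 1, 0.42 in cow 2 and 0.27 in cow 3. Across probes, which are not independent replicates, the ratios of cows 2 and 3 had a Pearson correlation of 0.78, those of cows 1 and 2 of 0.19 and those of cows 1 and 3 of 0.28; by rank (Spearman) these were 0.61, 0.03 and 0.14. Limma's F-test that the ratios of the 3 cows were equal called 15430 probes (47.4%) at an adjusted p under 0.05. It sets the cows against the technical error of the dye exchange alone, with 1 RNA pair per cow, and so does not tell a difference between animals from one between RNA preparations. INHBA and INHA, which encode inhibin and activin subunits of granulosa cells, were chosen after their values were seen: INHBA had ratios of -0.40, 0.12 and 1.48 and INHA of 0.20, -0.25 and 1.40 in cows 1, 2 and 3. In cow 3 the granulosa marker list as a whole had a median of 0.08. VIM of the theca and stromal list also had 1.52 in cow 3, where that list's median was 0.05. Whether other cells came along with the oocytes of cow 3 was not tested.

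A dye term in the same fit called 20998 probes (64.6%) at an adjusted p under 0.05. Its SD over probes was 0.23, against 0.24 for the mean ratio of antagonist over control. The exchange of dyes is meant to balance this effect within each cow, but the balance may not be complete. Across probes, the mean ratios of cows 2 and 3 correlated at -0.20 and -0.09 with the dye effect of cow 1. Those of cow 1 correlated at 0.13 with the dye effect of cow 2. On single orientations the ribosomal protein list had medians of 0.30 on the 3 arrays with control in Cy5 and 0.24 on the 3 with antagonist in Cy5.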

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

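The tests of the shared slide and of other probes of the same genes were chosen after related values had been seen.

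Cows 2 and 3 shared much of their ratios of antagonist over control (r = 0.78) and cow 1 less. Noisier spots in cow 1 were argued against, since among the brightest 10842 probes the correlation of cows 2 and 3 still exceeded the mean correlation of cow 1 with them by 0.59. A gene-specific dye effect left in the means was argued against too, because the partial correlation of cows 2 and 3, given the dye effect measured on cow 1's arrays, was 0.78. So was a shared slide: after that dye effect was subtracted, arrays of cows 2 and 3 on different slides, as inferred from the scanner files, and in opposite orientation correlated at 0.73. Differences between the animals, or between RNA amplifications, may underlie the pattern and remain open, since each cow gave 1 RNA pair.

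The ribosomal protein genes, higher as a group by camera's preset correlation but not with an estimated one (adjusted p = 0.86) or by fry (adjusted p = 0.32), were weighed against bias; 17 of the 67 had negative ratios. Their median of 0.23 lay at percentile 100 of 10000 random lists matched on RefSeq gene span, although ratios fell with gene span over all genes (Spearman's rho -0.16 across genes). It also lay at percentile 100 of lists matched on spot brightness. That match used ratios that loess had already freed of most trend with brightness (Spearman's rho -0.05 across genes). Without loess the median was 0.12, with an adjusted p of 0.030 by camera's preset correlation. The list's median was above 0 on 6 of 6 arrays, in both dye orientations. These values argue against gene span or dye as the whole cause, and against a trend with brightness left after loess. Transcript length, base composition, hybridisation to ribosomal pseudogenes and the antagonist itself stay open. Both RNAs of a cow came from separate oocyte collections, at least a month apart. Differences of collection or RNA amplification therefore cannot be told apart from the antagonist.

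More probes were higher than lower at 1.5-fold and unadjusted p under 0.05, 630 against 163. The excess varied with the processing: it was 634 against 17 with a trended, robust variance and 1372 against 1046 without cow 1. On the arrays with antagonist in Cy5, which shared a slide, it turned to 744 against 905. Those with control in Cy5 gave 1701 against 569. In these subsets the dye effect is not cancelled, and orientation is in part confounded with slide. Of the probes past 1.5-fold in a single cow, 74.2% were higher in cow 1, 51.2% in cow 2 and 63.3% in cow 3, while the share of probes above background was larger in the control of cow 1 (70.4% against 68.6%) and smaller in those of cows 2 (64.8% against 68.6%) and 3 (61.2% against 70.2%). The bound set beforehand against a smaller share above background in the control RNA as the cause was met, but it rested on cow 1 alone, which was judged too little after the values were seen, so this cause stays open. Among the 166 higher probes with another probe of the same gene, the median of the other probes' ratios was 0.35 of that of the counted probes, and 34.9% of the other probes were past 1.5-fold in the same direction. For the 51 lower probes with another probe these values were 0.21 and 13.7%. The counted probes were picked for their size, which by itself tends to leave the other probes' ratios smaller. The 0.35 of the higher probes lies between the values set for a signal of single probes and for one of whole transcripts, so these cannot be told apart.

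Positive control spots, which no comparison used, were above background: 10 of 10 E1A control sequences exceeded the negative controls in all 12 channel readings. Their mean log2 Cy5 over Cy3 ratios reached 2.76 in size, with a median SD of 0.37 over the 6 arrays. This SD was smaller than that of ratios turned to antagonist over control for 9 of the 10 sequences; the other had a mean ratio of 0.06.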

How the results depend on the processing

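Trimmed mean intensities were the one alternative chosen after seeing the data. The 0 probes at adjusted p under 0.05 by limma (4143 at an unadjusted p under 0.05) stood under every alternative of background, normalization, filter, variance model, slide, the authors' ratios and each cow left out (0 to 0). They became 848 with the cow as a random replicate block over 6 arrays (consensus correlation 0.77), 2446 with the arrays as independent values, which counts technical repeats as replicates, and 8 in the unpaired fit with no replicate block. With 1 dye orientation they became 109 (control in Cy5) and 186 (antagonist in Cy5), where by construction the dye effect is not cancelled. The arrays with antagonist in Cy5 also shared a slide. The 793 probes at 1.5-fold became 2454 on the shared slide, where arrays counted as independent values and cow 2 weighed most. They became 2270 and 1649 in those orientations, and 434 to 2418 with a cow left out. The cause was not tested. Median centring without loess moved the higher share from 79.4% to 62.6%; it was 97.4% with trended, robust eBayes, 58.6% on the shared slide, 74.9% and 45.1% in those orientations, and 56.7% to 88.0% with a cow left out. The 1 list that passed became 2 on the shared slide, 0 with an estimated correlation, 0 with fry, and 2 to 3 with a cow left out. The ribosomal protein list kept its direction in all alternatives and its call in the 20 that used camera's preset correlation (adjusted p 5.3e-08 to 0.030), but its median of 0.23 had an adjusted p of 0.86 with an estimated correlation and 0.32 with fry. Several alternatives leave the ratios as they are and so could not turn its direction: Aquantile, the trended variance, the block, independent and unpaired fits, and both other set tests. The 20 calls all rest on the same preset correlation and are not separate tests of it. The mean correlation between cows (0.42) was 0.19 to 0.78 with a cow left out. The dye and cow counts stayed within 1.5 times. Of 1038 values of the 55 named genes, 935 moved by less than the SD over cows without passing correction, 35 moved further, 68 passed correction in the same direction, and no gene at an unadjusted p under 0.05 changed sign. Those 68 come from the block, independent and unpaired fits and the single dye orientations, since no probe passed elsewhere. Of all 55 genes, 48 kept their sign in every alternative. In part this stability was fixed in advance. Aquantile, both filter settings, the trended variance and the block, independent and unpaired fits leave a gene's ratio as it is. Flipping the sign of whole cows gives 4 splits of the samples, too few for a share under 0.05. At adjusted p all 4 gave 0 probes, with 0 the highest other; for the 1.5-fold count, 1 of 4 gave as many as the real 793, with 227 the highest other; for lists 3 of 4 reached the real 1, with 3 the highest other; and for the dye 1 of 4 reached 20998, with 0 the highest other. Dim probes are limited by signal over background.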

Other observations

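Some lists that did not pass as groups held members that passed when adjusted over the list alone. The genes named here were chosen after their values were seen, and none passed over all probes. Of the 27 lists, 8 held such members, and the adjustment did not extend across lists. Among 69 spliceosome genes 6 passed, in both directions: SNRPC had a log2 ratio of 1.54 ± 0.31 (SD over 3 cows), SNRPD1 1.22 ± 0.28, SFRS8 0.79 ± 0.053 and PRPF6 0.93 ± 0.25, while HNRNPU had -0.51 ± 0.13 and PRPF4 -0.37 ± 0.072. The list's median was -0.06 and its mean 0.03, and in 6 of 27 lists the median, the mean and the direction of the test did not all share a sign. Of 41 actin, tubulin and spindle genes 7 passed: TACC3, a spindle protein, had 1.23 ± 0.52, the tubulins TUBB, TUBB2C and TUBB2B had 0.80, 0.70 and 0.69, RHOA had 0.45 ± 0.16 and CDC42 -0.40 ± 0.072, besides SPIRE2. Of 40 meiotic cell cycle genes 2 passed, CDC20, the activator of the anaphase-promoting complex, at 0.86 ± 0.18 and CDCA8, a chromosomal passenger protein, at 0.51 ± 0.11. Of 32 genes of PI3K, AKT and TGF-beta signalling TSC2 had 0.55 ± 0.044 and SMAD1 -0.31 ± 0.040.

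Of the genes that respond to LH and EGF-like factors in follicles, those named here were also chosen after their values were seen. The list had a median of -0.06 over 19 genes (camera adjusted p = 0.40), and 14 lay below 0. SPRY2 had ratios of -0.0098, -0.79 and -0.78, HAS2 -0.0026, -0.98 and -0.38, SNAP25 0.02, -1.05 and -0.68, and PTGS2 0.53, -0.97 and -0.29 in cows 1, 2 and 3. None had an unadjusted p under 0.05 by limma for antagonist against control.

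Over 3004 genes with at least 2 tested probes, the ratios of the 2 brightest probes correlated at 0.44 across genes.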
